A study of Mus musculus with 6 samples.

How the data were processed

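Total RNA of sorted AI4 CD8 T cells was hybridised to 6 single-colour Affymetrix Mouse Gene 1.0 ST arrays, 3 from AI4 mice and 3 from Rip-B7xAI4 mice. Per the labels' protocols, single-cell suspensions of pancreata were pooled and the cells were sorted with an antibody to CD8 and a tetramer of the peptide MimA2 on H-2Db, and RNA was purified on a column kit and labelled with biotin. Per the submitters' processing notes, the authors used Affymetrix Expression Console, and its version and summarisation algorithm are not given in the sources used here. The authors deposited 1 normalized value per probe and array. That these deposited values are log2 was read from their range, because the sources used here do not state the scale. Array medians lay between 5.94 and 6.10, so the values were used as deposited with no further normalization. The spread differed between arrays, with an interquartile range of 1.71 to 1.95 in AI4 and 1.81 to 2.13 in Rip-B7xAI4. Quantile normalization, which evens this out, was run as an alternative.

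The table held 28325 probes with 0 missing values. Probes were named through the platform annotation, which gave 21760 probes with 1 gene symbol, 1621 with several and 4944 with none. Of the named probes, 21669 were matched by gene ID to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No gene was named from a probe with several symbols, and no coordinates were used. For the 994 genes with more than 1 probe, the probe with the highest mean over all arrays was kept, which left 19929 genes. The 30% of genes with the lowest mean were not tested, which set the limit at a mean log2 of 5.471 and left 13950 genes tested and 5979 not tested. No measure of background was used here, so how far the values of dim probes lie above it is not known.

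Groups were taken from the sample titles. Log2 values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 term for the group and no block. Differences are Rip-B7xAI4 minus AI4, tests were two-sided, and p was adjusted by Benjamini and Hochberg over all genes tested, with 0.05 as the limit. An unadjusted limit of 0.01 was counted beside it. Standard errors are those of limma, which shares information on the spread between genes. Array depth has no count behind it, so the 3 arrays per group set the precision.

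Before the data were examined, 28 gene lists were fixed, 17 by function and 11 of cell type markers. Of these, 27 had at least 4 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with the correlation estimated for each list and with limma's fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. With an estimated correlation camera also bases its p on the few residual degrees of freedom of the arrays, and with a preset one on the many genes. A p can therefore rise even where the estimate lies below the preset value. Members of each list were also adjusted over the list alone. Some genes belong to more than 1 list.

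The genes named were fixed by a rule at the same time. It takes up to 10 genes higher and 10 lower, by size among those past the limit or, where fewer than 5 pass, by smallest p in that direction. It also takes up to 4 tested members of each list by smallest p, and a set of T cell, beta cell, acinar, B cell and myeloid genes that is always named. Unnamed transcript models were passed over. Apoe, 1 of 20 further myeloid genes, was picked for naming after its values were seen, as were the genes of the families described at the end and the myeloid genes named for the fit without Rip-B7xAI4 replicate 2.

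Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array, quantile normalization, median centring, no filter or a 50% filter on dim genes, the mean of a gene's probes, eBayes with trend and robust, array weights, and every probe tested on its own. A pseudocount alternative was fixed for linear values and did not apply. After the data were examined, 2 settings were added: the fit without Rip-B7xAI4 replicates 1 and 3 together, and a fit with the mean of the myeloid marker list as a covariate. All 10 splits of the 6 arrays into groups of 3 were fitted in the same way.

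The fit was tested on simulated data, in 20 sets of 13950 genes of which 200, picked at random, were changed. Each gene's spread was the value limma gives after sharing information between genes. That spread is more even than the observed one, so the recovered shares may be too high for the real arrays. It recovered 20.2% of genes changed by 1 on the log2 scale, 85.2% of those changed by 2, 96.2% of those changed by 3 and 98.6% of those changed by 4. False calls made up 5.60% of all calls, and camera called 0 lists where nothing was changed. The simulated genes were drawn independently of each other, so neither value tests the methods on correlated genes. In the real arrays the estimated correlation was 0.564 for cell division genes and 0.748 for myeloid markers. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.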

Results

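Gene expression was measured in CD8 T cells that carry the AI4 antigen receptor, a transgenic receptor for a beta cell antigen, after these cells had been sorted from mouse pancreas. The cells came either from AI4 mice, which developed type 1 diabetes, or from Rip-B7xAI4 mice, which were resistant to it. Rip-B7x is a transgene that places B7x (Vtcn1), an inhibitory ligand of the B7 family, under the rat insulin promoter and so on beta cells. Each group had 3 arrays, labelled as biological replicates, and each array held total RNA from pooled pancreata, with the number of mice not given in the sources used here. Median log2 expression per array lay between 5.94 and 6.10. With 3 arrays per group, the number of arrays limits the precision of every value.

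The comparison asks how AI4 T cells in the pancreas differ in gene expression when beta cells carry B7x. The transgene goes together with resistance to diabetes here. An effect of B7x on the T cells therefore cannot be told apart from an effect of the disease state of the mice. Cells sorted from Rip-B7xAI4 pancreas held more RNA for Ccl3, a chemokine that activated CD8 T cells secrete. Ccl3 (probe 10389231) rose from 5.84 ± 0.26 (SD, n = 3) log2 in AI4 to 9.73 ± 0.26 (SD, n = 3) in Rip-B7xAI4. Its 3 AI4 values, 5.54, 5.99 and 6.00, lay below the medians of their arrays (6.10, 6.08 and 6.05), and no measure of background was used here, so no fold is given. The log2 difference was 3.89 ± 0.22 (SE), with an adjusted p = 0.00973 by limma, and all 3 Rip-B7xAI4 arrays lay above all 3 AI4 arrays. Ccl3 was the only 1 of 13950 tested genes to pass an adjusted p of 0.05, and 0 genes fell. Its adjusted p was 0.0451 without AI4 replicate 1 and 0.0269 without Rip-B7xAI4 replicate 2. It did not pass without AI4 replicate 2 (0.0687), AI4 replicate 3 (0.0591), Rip-B7xAI4 replicate 1 (0.151) or Rip-B7xAI4 replicate 3 (0.0698). Over all alternatives its log2 difference lay between 3.74 and 4.19 and its adjusted p between 0.00302 and 0.484. Without adjustment, 1218 genes had p under 0.05 in limma and 293 had p under 0.01, of which 233 were higher and 60 lower in Rip-B7xAI4. The higher share of these was 79.5%, and 65.6% after quantile normalization. The groups did not overlap for 17.9% of the tested genes, against 10% by chance, with all Rip-B7xAI4 arrays above all AI4 arrays for 836 genes and below them for 1656. The median difference over all tested genes was -0.10 on the log2 scale.

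The next genes in order of p did not pass, with adjusted p of 0.145 or more. Among those higher in Rip-B7xAI4, Plek (pleckstrin) differed by 3.86 ± 0.37 (SE) on the log2 scale and Lgals1 (galectin-1) by 1.48 ± 0.15. Gzma, the protease granzyme A of cytotoxic granules, differed by 2.91 ± 0.35, and Zdhhc2, a palmitoyltransferase, by 3.23 ± 0.37. Prc1 and Knl1, proteins of the mitotic spindle and kinetochore, differed by 2.23 ± 0.27 and 2.14 ± 0.26, and Shcbp1 by 2.45 ± 0.29. D17H6S56E-5 differed by 1.90 ± 0.24. Bcl2a1c differed by 2.74 ± 0.30, a value that is uncertain because near-identical copies of this gene can share probe signal.

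Among genes lower in Rip-B7xAI4, 10 are named by the same rule and none passed. Satb1, a chromatin organizer of T cells, differed by -1.13 ± 0.20 (SE), and Foxp1, a transcription factor of resting T cells, by -1.17 ± 0.22. Slamf6, a receptor of the SLAM family, differed by -1.66 ± 0.29 and the scavenger receptor gene Cd163l1 by -2.02 ± 0.34. Dzip1 differed by -1.64 ± 0.23, Lysmd1 by -1.24 ± 0.17 and Mdm4 by -1.21 ± 0.19. Acp5 differed by -1.18 ± 0.21, Stx2 by -1.02 ± 0.18 and Pfkfb2, a regulator of glycolysis, by -1.24 ± 0.23.

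**Figure D1:**
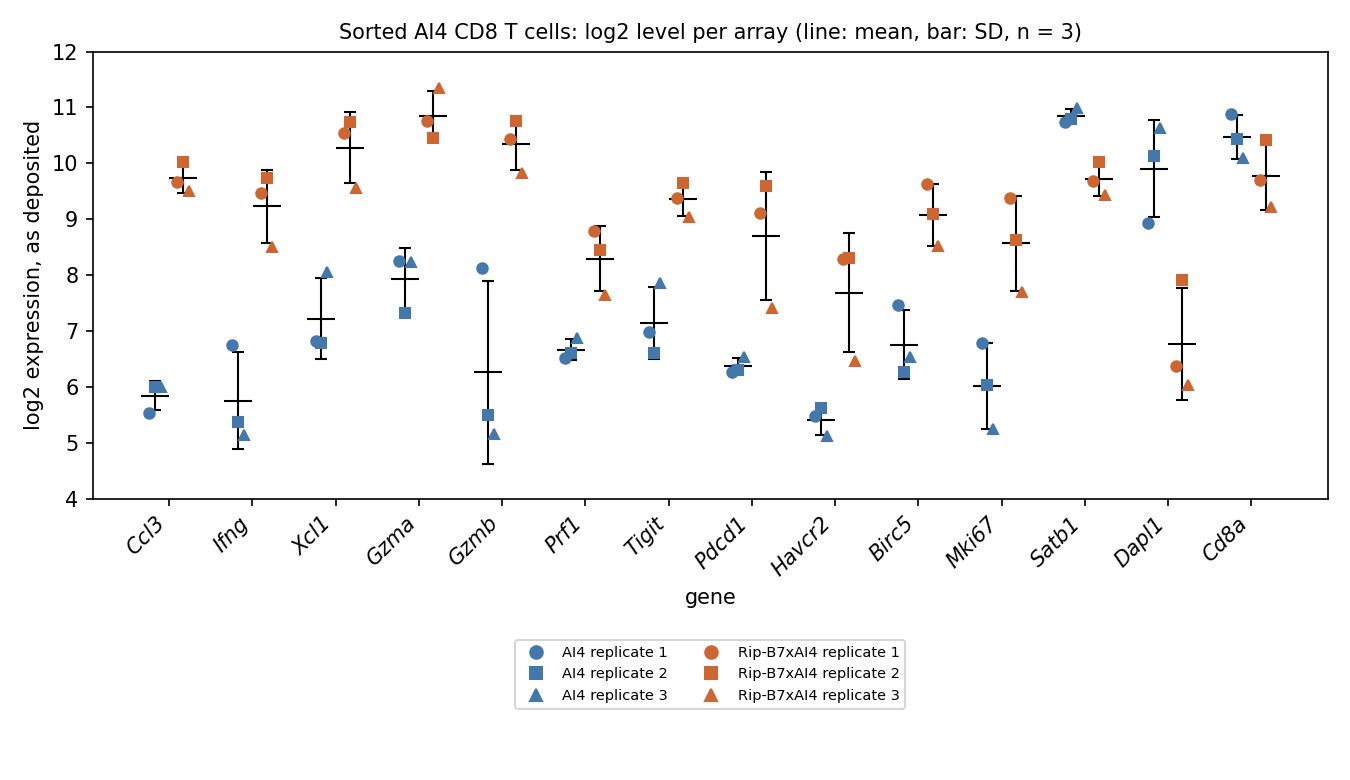
Log2 expression as deposited (vertical axis) of 14 named genes (horizontal axis) in each array, blue for AI4 and orange for Rip-B7xAI4, with a different symbol for each replicate, a line for the group mean and a bar for the SD (n = 3). Ccl3 lies between 5.54 and 6.00 in AI4 and between 9.51 and 10.02 in Rip-B7xAI4, while the groups overlap for Cd8a.

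Cytotoxic effector genes were higher in the cells sorted from Rip-B7xAI4 mice, as a group. Of 17 tested members, 6 rose and 0 fell when p was adjusted over the list alone, and 0 passed over all genes. Gzma, Gzmb, Prf1, Fasl and Serpinb9 were among them. Gzmb (granzyme B) differed by 4.08 ± 0.77 (SE), with AI4 at 6.26 ± 1.63 (SD, n = 3) and Rip-B7xAI4 at 10.34 ± 0.47 (SD, n = 3). Prf1, the pore-forming perforin, differed by 1.63 ± 0.31, Fasl, the ligand of the death receptor Fas, by 1.97 ± 0.33, and Serpinb9, an inhibitor of granzyme B, by 1.74 ± 0.24. The list passed camera with a mean difference of 1.09 (adjusted p = 5.91e-09), but not with the correlation estimated from the data (adjusted p = 0.0979 with an estimated correlation). That estimate was 0.0446, against the preset 0.01. The loss cannot be put down to the correlation alone, because the estimated form also bases its p on the few arrays. The list passed fry (adjusted p = 0.0268), but not fry with the replicate block (adjusted p = 0.0597). Mean expression of myeloid markers was 8.93 and 8.80 in Rip-B7xAI4 replicates 1 and 3 and 6.28 in replicate 2, while the cytotoxic list stood at 8.34, 8.08 and 8.13 in the same order and between 6.86 and 7.29 in AI4.

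Effector cytokine and chemokine genes were higher as well. Of 16 tested members, 5 rose and 0 fell adjusted over the list alone, against 1 over all genes. Ccl3, Ccl5, Ifng and Xcl1 were among them. Ifng (interferon gamma) differed by 3.47 ± 0.51 (SE), from 5.76 ± 0.87 (SD, n = 3) in AI4 to 9.23 ± 0.65 (SD, n = 3). Xcl1, a chemokine for cross-presenting dendritic cells, differed by 3.06 ± 0.45 and Ccl5 by 1.32 ± 0.19. Tnf differed by 0.61 ± 0.34 and did not pass. Il2 was among the genes too dim to test, at 5.23 ± 0.19 (SD, n = 3) in AI4 and 5.13 ± 0.09 (SD, n = 3) in Rip-B7xAI4. On average the list was 0.83 higher (camera adjusted p = 9.85e-06; adjusted p = 0.0979 with an estimated correlation). That estimate was -0.0374, below the preset 0.01, so a higher correlation was not what ended the pass (unadjusted camera p from 2.55e-06 to 0.00725). The list passed fry (adjusted p = 0.00240).

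Inhibitory receptor genes were also higher in Rip-B7xAI4. Of 17 tested members, 8 rose and 0 fell adjusted over the list alone, and 0 over all genes. Tigit differed by 2.21 ± 0.35 (SE), Entpd1 by 2.48 ± 0.40, Klrc1 by 3.26 ± 0.70, Havcr2 by 2.28 ± 0.51, Pdcd1 by 2.33 ± 0.54 and Lag3 by 1.57 ± 0.48. Ctla4 and Btla did not pass, with differences of 0.67 ± 0.79 and 0.60 ± 0.46. The list mean was 1.12 higher (camera adjusted p = 9.82e-08; adjusted p = 0.126 with an estimated correlation). The count fell to 5 without AI4 replicate 1, to 5 without AI4 replicate 2 and to 4 without Rip-B7xAI4 replicates 1 and 3 together, where the remaining Rip-B7xAI4 array is assumed to vary like the AI4 arrays. The list passed camera at the preset correlation in each of these fits, with a mean of 1.15 in the last. With the myeloid marker mean as a covariate the count was 6 and the list mean 1.13. Lag3 then differed by 2.49 ± 0.52, more than without the covariate, and Entpd1 by 1.86 ± 0.49, less than without it.

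Early genes induced by the antigen receptor, costimulatory receptors and anergy-associated genes had smaller mean differences. Of 30 tested early genes, 0 passed adjusted over the list alone, although the list mean was 0.39 higher (camera adjusted p = 0.000681; adjusted p = 0.352 with an estimated correlation). The early gene list had a mean of 0.15 and did not pass without Rip-B7xAI4 replicate 1 (adjusted p = 0.0663, with 4.08e-05 to 0.551 over all alternatives). Its mean was 0.25 without Rip-B7xAI4 replicates 1 and 3 together (adjusted p = 0.0886) and 0.23 with the mean of the myeloid markers as a covariate (adjusted p = 0.159). Egr2 differed by 1.64 ± 0.48 (SE), Nr4a2 by 1.94 ± 0.58, Egr1 by 0.60 ± 0.47 and Nr4a1 by 0.56 ± 0.45. In the list of costimulatory and cytokine receptors, 0 of 26 passed adjusted over the list alone and the mean was 0.33 higher (camera adjusted p = 0.0173; adjusted p = 0.352 with an estimated correlation). It did not pass without AI4 replicate 1 (adjusted p = 0.132), without Rip-B7xAI4 replicate 2 (adjusted p = 0.0748), after quantile normalization (mean 0.22, adjusted p = 0.0870) or with the 50% filter (adjusted p = 0.118), with 0.00193 to 0.551 over all alternatives, and the mean was 0.52 without AI4 replicate 3. Of its members 15 had a positive and 11 a negative difference. Il18rap differed by 1.40 ± 0.43, Il2rb by 1.08 ± 0.34 and Ifngr2 by -1.35 ± 0.42. In the list of anergy-associated genes, Nrp1 alone of 18 rose adjusted over the list alone, by 1.39 ± 0.25, and the list did not pass camera (mean 0.26, adjusted p = 0.0748). The count was 0 without AI4 replicate 2 or without Rip-B7xAI4 replicate 1, 2 without AI4 replicate 3 and 3 without Rip-B7xAI4 replicate 3, where the list passed camera (adjusted p = 0.0424, with 0.0202 to 0.389 over all alternatives). It was 4 with array weights and 0 with the covariate, where Nrp1 differed by 0.93 ± 0.29 and the list mean was 0.20, and the list also passed with no filter on dim genes (adjusted p = 0.0202).

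Genes of naive and memory T cells were lower in Rip-B7xAI4. Of 19 tested members, 4 fell and 0 rose adjusted over the list alone, and 0 passed over all genes. These were Satb1, Foxp1, Dapl1 and Igfbp4. Dapl1 differed by -3.12 ± 0.61 (SE), from 9.90 ± 0.87 (SD, n = 3) in AI4 to 6.78 ± 1.00 (SD, n = 3) in Rip-B7xAI4. Il7r, the interleukin-7 receptor chain, differed by -1.12 ± 0.48 and did not pass. Their mean difference was -0.70 (camera adjusted p = 9.95e-05; adjusted p = 0.346 with an estimated correlation). By array, the list mean was 8.24, 8.64 and 9.16 in AI4 and 8.10, 8.21 and 7.64 in Rip-B7xAI4. The lowest AI4 array and the highest Rip-B7xAI4 array thus nearly met. The count was 2 without Rip-B7xAI4 replicate 1, 0 without Rip-B7xAI4 replicates 1 and 3 together and 0 with the myeloid covariate, and the mean was -0.46 without AI4 replicate 3. The list passed camera at the preset correlation in each of these fits, with a mean of -0.47 without Rip-B7xAI4 replicates 1 and 3 together and -0.48 with the covariate, where the median SE of its genes was 0.562 against 0.389 without it. Dapl1 differed by -1.95 ± 0.64 with the covariate.

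Effector differentiation genes were higher, with 3 of 19 rising and 0 falling adjusted over the list alone. Id2 differed by 3.08 ± 0.44 (SE), Bhlhe40 by 2.80 ± 0.44 and Zeb2 by 1.44 ± 0.38, all transcriptional regulators of effector T cells. By array Zeb2 stood at 7.47 and 7.69 in Rip-B7xAI4 replicates 1 and 3, where myeloid markers were high, at 6.39 in replicate 2 and at 5.35 to 6.02 in AI4. With the myeloid marker mean as a covariate it differed by 0.59 ± 0.32 and did not pass, while Id2 and Bhlhe40 passed. The list mean was 0.84 higher (camera adjusted p = 9.49e-08; adjusted p = 0.126 with an estimated correlation), and the count was 5 without Rip-B7xAI4 replicates 1 and 3 together, 6 under median centring and 9 with array weights. Of 21 trafficking and residence genes, 4 rose and 0 fell adjusted over the list alone. The integrin genes Itgb1 and Itgal differed by 1.85 ± 0.29 and 1.35 ± 0.26, and the chemokine receptor genes Ccr2 and Cxcr6 by 2.10 ± 0.38 and 2.21 ± 0.49. With the covariate Ccr2 differed by 1.18 ± 0.26. That list had a mean of 0.46 (camera adjusted p = 0.00536; adjusted p = 0.352 with an estimated correlation), and 0 members rose without Rip-B7xAI4 replicates 1 and 3 together or with the myeloid covariate. The list passed camera at the preset correlation in both of these fits, with means of 0.45 and 0.44, and the median SE of its genes was 0.545 with the covariate against 0.412 without it. Without AI4 replicate 1 its mean was 0.29 and it did not pass (adjusted p = 0.101, with 0.000243 to 0.414 over all alternatives).

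Cell division genes had a positive difference in 37 of 38 tested members. Adjusted over the list alone, 17 rose and 0 fell, and 0 passed over all genes. Kif11, a spindle motor, differed by 3.17 ± 0.53 (SE), Birc5 (survivin) by 2.32 ± 0.40, Cenpe by 2.29 ± 0.42 and Ube2c by 1.10 ± 0.20. Mki67, the Ki-67 proliferation antigen, differed by 2.55 ± 0.53. The list mean was 1.19 higher (camera adjusted p = 1.29e-20; adjusted p = 0.245 with an estimated correlation). By array, the list mean was 6.95, 6.21 and 6.22 in AI4 and 8.17, 7.65 and 7.12 in Rip-B7xAI4. The count was 8 without any 1 of AI4 replicate 2, AI4 replicate 3, Rip-B7xAI4 replicate 1 or Rip-B7xAI4 replicate 2, 4 without Rip-B7xAI4 replicates 1 and 3 together, 0 with the myeloid covariate and 29 with array weights. The list passed camera at the preset correlation in each of these fits, with a mean of 1.19 without Rip-B7xAI4 replicates 1 and 3 together and 1.12 with the covariate, where the median SE of its genes was 0.546 against 0.398 without it.

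Metabolic and stress genes passed in part as lists and not as single genes. Of 31 oxidative phosphorylation genes, 0 passed adjusted over the list alone, while the list mean was 0.46 higher (camera adjusted p = 5.91e-09; adjusted p = 0.126 with an estimated correlation) and 0.26 higher after quantile normalization. Cox7b, a subunit of cytochrome oxidase, differed by 0.70 ± 0.17 (SE) and Uqcrq by 0.65 ± 0.20. Of 20 heat shock and unfolded protein response genes, 0 passed adjusted over the list alone, and the mean was 0.35 higher (camera adjusted p = 0.000391; adjusted p = 0.327 with an estimated correlation). It was 0.21 after quantile normalization and 0.20 without Rip-B7xAI4 replicate 1. The endoplasmic reticulum chaperone genes Hspa5 and Calr differed by 0.96 ± 0.24 and 0.89 ± 0.29. Glycolysis genes did not pass as a list (mean 0.15, camera adjusted p = 0.113), with 0.0399 to 0.551 over all alternatives. The exceptions were without Rip-B7xAI4 replicate 3 (mean 0.25, adjusted p = 0.0423) and with no filter on dim genes (adjusted p = 0.0399). The glycolysis mean was 0.26 without Rip-B7xAI4 replicates 1 and 3 together and 0.25 with the myeloid covariate. In this list Pdk1 differed by -1.06 ± 0.27 and Pfkp by 0.90 ± 0.25. The lists of apoptosis genes (mean 0.08, adjusted p = 0.400) and of sterol and fatty acid synthesis genes (mean 0.05, adjusted p = 0.450) did not pass either, and in both the median was below 0, at -0.014 and -0.004, while the mean and camera were above 0. Bcl2l11, which encodes the death protein Bim, differed by 0.71 ± 0.53.

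Interferon response genes were higher as lists. Of 22 tested type I interferon response genes, 1 rose adjusted over the list alone, Ifi27l2a, by 2.31 ± 0.33 (SE). The list had a mean of 0.60 (camera adjusted p = 1.16e-05; adjusted p = 0.327 with an estimated correlation), but 0.09 without Rip-B7xAI4 replicates 1 and 3 together, with adjusted p = 0.741 (2.14e-09 to 0.753 over all alternatives), and 0.06 with the myeloid covariate, with adjusted p = 0.753. By array the list stood at 7.67 and 7.52 in Rip-B7xAI4 replicates 1 and 3, where myeloid markers were high, and at 6.83 in replicate 2. The count was 3 without AI4 replicate 1, 2 without AI4 replicate 3, 4 without Rip-B7xAI4 replicate 2, 3 with array weights, and 0 without Rip-B7xAI4 replicates 1 and 3 together or with the covariate, where Ifi27l2a differed by 2.17 ± 0.50.

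Of 22 interferon-gamma response genes, 1 rose adjusted over the list alone, the immunoproteasome gene Psmb9, by 0.98 ± 0.18 (SE). That list had a mean of 0.16 (camera adjusted p = 0.0225; adjusted p = 0.214 with an estimated correlation), and 0 members passed without AI4 replicate 2, without AI4 replicate 3, without Rip-B7xAI4 replicate 1, without Rip-B7xAI4 replicate 3 or after quantile normalization. By array it stood at 8.29 and 8.15 in Rip-B7xAI4 replicates 1 and 3, where myeloid markers were high, and at 7.98 in replicate 2, within the AI4 range of 7.87 to 8.09. The mean was 0.005 without Rip-B7xAI4 replicates 1 and 3 together (adjusted p = 0.401) and -0.002 with the myeloid covariate (adjusted p = 0.255), and 0 members passed in either, with Psmb9 at 1.03 ± 0.29 under the covariate. The list itself did not pass without AI4 replicate 3 (adjusted p = 0.119), Rip-B7xAI4 replicate 1 (mean 0.09, 0.0570) or Rip-B7xAI4 replicate 3 (0.0506). Nor did it pass after quantile normalization (mean 0.05, adjusted p = 0.221), with array weights (mean 0.10, adjusted p = 0.111) or with the 50% filter (adjusted p = 0.118), with 0.00111 to 0.401 over all alternatives.

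**Figure D2:**
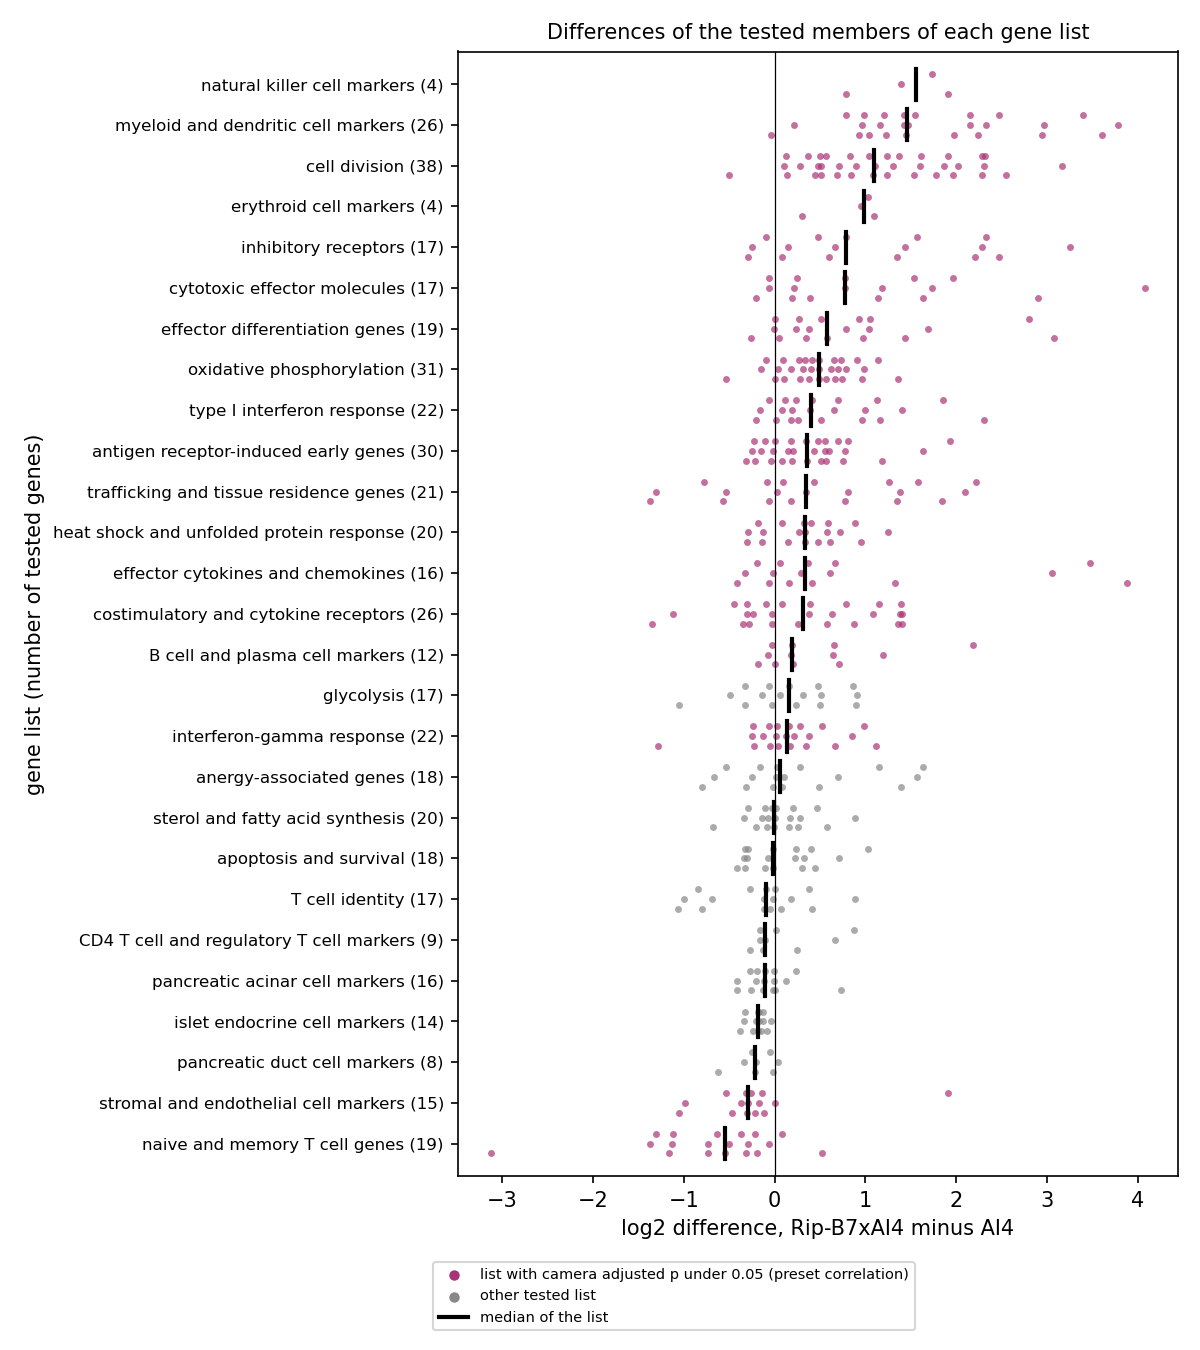
Log2 difference between Rip-B7xAI4 and AI4 (horizontal axis) of each tested gene (point) in 27 gene lists (vertical axis), with a black line at the median of each list. Purple points belong to the 18 lists that passed camera with a preset correlation, of which 16 were higher and 2 lower, and with an estimated correlation 0 lists passed.

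Markers of T cells and of other pancreatic cells were read to describe the sorted cells. T cell identity genes did not pass as a list (mean -0.18, adjusted p = 0.513). Cd8a differed by -0.69 ± 0.35 (SE) and Cd3e by 0.88 ± 0.42. Cd8b1 was at 11.10 ± 0.54 (SD, n = 3) in AI4 and 10.10 ± 0.61 (SD, n = 3) in Rip-B7xAI4. Vtcn1, which encodes B7x itself, was at 6.10 ± 0.18 (SD, n = 3) in AI4 and 6.23 ± 0.10 (SD, n = 3) in Rip-B7xAI4, and since the transgene is placed on beta cells its level in the sorted cells does not check the labels. Markers of acinar cells (mean -0.07, adjusted p = 0.578), duct cells (mean -0.21, adjusted p = 0.171) and islet endocrine cells (mean -0.20, adjusted p = 0.0778) did not pass. The islet list passed without AI4 replicate 3 (mean -0.30, adjusted p = 0.0140) or without Rip-B7xAI4 replicate 3 (mean -0.26, adjusted p = 0.0305). It also passed with no filter on dim genes (adjusted p = 0.0411), with 0.0140 to 0.613 over all alternatives. The direction camera gave the acinar list turned under quantile normalization. The digestive enzyme gene Prss2 differed by -0.11 ± 0.17 and the insulin gene Ins2 by -0.04 ± 0.23. The direction of Ins2 turned under quantile normalization (0.03) and under median centring (0.02).

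Myeloid and dendritic cell markers were high in Rip-B7xAI4 replicates 1 and 3. The mean over 26 tested markers was 8.93 and 8.80 in these arrays, 6.28 in Rip-B7xAI4 replicate 2, and 6.36, 6.00 and 6.35 in the AI4 arrays. Adjusted over the list alone, 2 markers rose, Itgax by 1.43 ± 0.23 (SE) and Cd68 by 2.15 ± 0.48. S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, differed by 3.61 ± 1.06 and 3.79 ± 1.08, and Lyz2 (lysozyme) by 2.33 ± 1.51. The list mean was 1.76 higher (camera adjusted p = 9.51e-13; adjusted p = 0.327 with an estimated correlation). The count was 24 without Rip-B7xAI4 replicate 2, 1 without AI4 replicate 1, and 0 without AI4 replicate 3, without Rip-B7xAI4 replicate 1 or without Rip-B7xAI4 replicate 3. With array weights it was 1 and the mean 1.09, and without Rip-B7xAI4 replicates 1 and 3 together it was 0 and the mean 0.04 (adjusted p = 0.912, with 4.47e-36 to 0.912 over all alternatives). With the myeloid marker mean as a covariate Cd68 differed by 0.98 ± 0.30.

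Erythroid, B cell and natural killer cell markers were also read array by array. Erythroid markers, with 4 tested genes, had a mean of 8.31 in Rip-B7xAI4 replicate 3 and between 6.09 and 6.77 elsewhere (mean difference 0.84, camera adjusted p = 0.0168; adjusted p = 0.352 with an estimated correlation). Without AI4 replicate 3 (adjusted p = 0.0659) or Rip-B7xAI4 replicate 3 (mean 0.22, 0.264) that list did not pass, nor with array weights (mean 0.42, 0.209), with 0.000401 to 0.849 over all alternatives. Its mean was 1.33 without Rip-B7xAI4 replicate 2, -0.13 without Rip-B7xAI4 replicates 1 and 3 together and -0.085 with the myeloid covariate. B cell markers had a mean of 6.89 in Rip-B7xAI4 replicate 1, 7.30 in replicate 3 and 6.09 in replicate 2 (mean difference 0.47, camera adjusted p = 0.0197; adjusted p = 0.352 with an estimated correlation). They did not pass without AI4 replicate 2 (adjusted p = 0.0601), AI4 replicate 3 (0.0561), Rip-B7xAI4 replicate 1 (0.0533), Rip-B7xAI4 replicate 3 (mean 0.20, 0.269) or with array weights (mean 0.23, 0.172), with 0.000235 to 0.569 over all alternatives. Their mean was 0.81 without Rip-B7xAI4 replicate 2, 0.81 with the 50% filter, -0.20 without Rip-B7xAI4 replicates 1 and 3 together and -0.20 with the covariate.

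The immunoglobulin gene Ighm differed by -0.03 ± 0.27 (SE), and by 0.04 under median centring. Natural killer cell markers had 4 tested genes, of which Klra3 and Fcer1g rose adjusted over the list alone, by 1.39 ± 0.27 and 1.73 ± 0.54. That list mean was 1.46 higher (camera adjusted p = 0.000391; adjusted p = 0.126 with an estimated correlation), and it stood at 8.32 and 8.44 in Rip-B7xAI4 replicates 1 and 3, 6.80 in replicate 2 and 6.19 to 6.78 in AI4. Without Rip-B7xAI4 replicates 1 and 3 together the mean was 0.41 (adjusted p = 0.24) and the count 0, and with the myeloid covariate they were 0.38 (adjusted p = 0.231) and 1, with Fcer1g at 0.73 ± 0.59, with adjusted p of 2.94e-07 to 0.24 over all alternatives. With no filter on dim genes the mean was 0.85 and the count 4, and the count was 0 with the 50% filter and 1 with array weights. It was 4 without Rip-B7xAI4 replicate 2 and 1 without AI4 replicate 1, AI4 replicate 2, AI4 replicate 3 or Rip-B7xAI4 replicate 1. Klra3 has near-identical relatives that can share probe signal, and Fcer1g is also a gene of myeloid cells.

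Stromal and endothelial markers were lower as a list (mean -0.22, camera adjusted p = 0.0151; adjusted p = 0.352 with an estimated correlation), with 0 of 15 passing adjusted over the list alone. The list did not pass without AI4 replicate 2 (adjusted p = 0.0571) or without Rip-B7xAI4 replicate 1 (adjusted p = 0.123), with 0.00416 to 0.353 over all alternatives. The mean was -0.35 with array weights, -0.36 without Rip-B7xAI4 replicates 1 and 3 together and -0.34 with the myeloid covariate. By array, the list mean was 6.50, 6.67 and 6.41 in AI4 and 6.28, 6.17 and 6.47 in Rip-B7xAI4, so the groups overlapped. The lead member, Pecam1, differed by -1.05 ± 0.31 (SE). Markers of CD4 and regulatory T cells did not pass (mean 0.11, adjusted p = 0.613), and their median was -0.10. Of the polyclonal T cell receptor variable genes, 1 was measured, Trbv1, which differed by 0.26 ± 0.29.

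**Figure D3:**
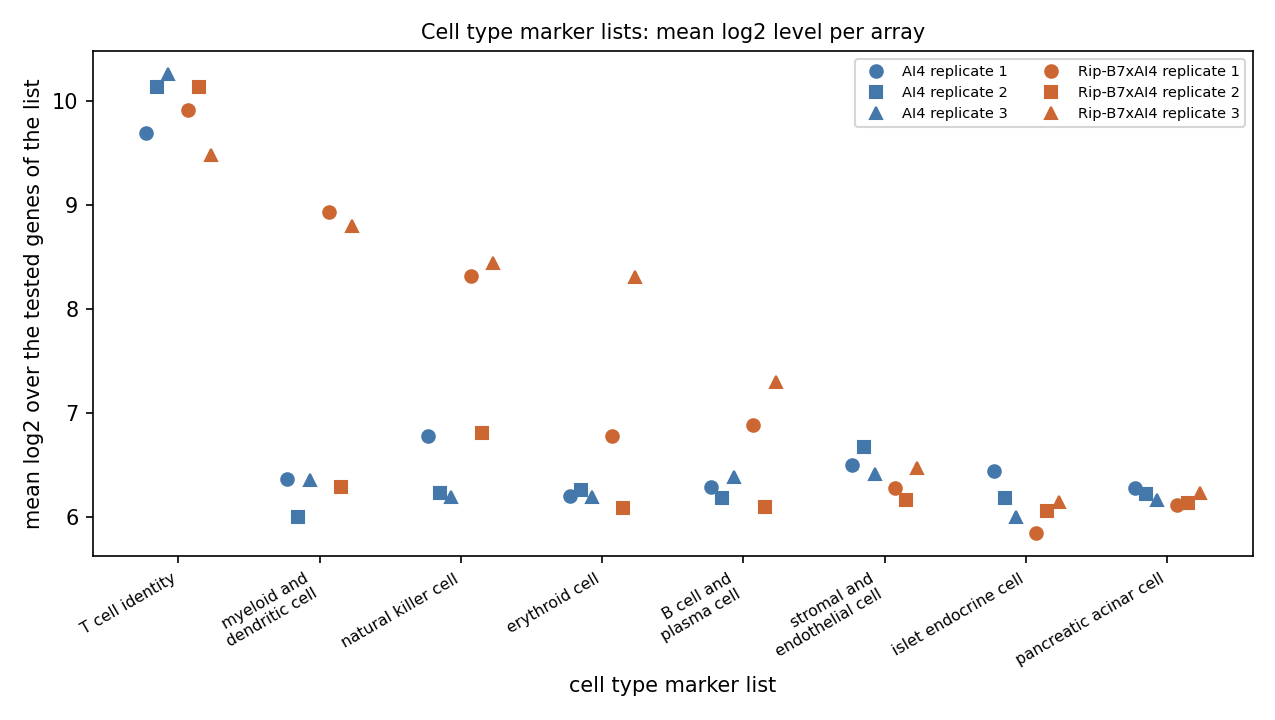
Mean log2 expression over the tested genes (vertical axis) of 8 cell type marker lists (horizontal axis) in each array, blue for AI4 and orange for Rip-B7xAI4, with a different symbol for each replicate. The myeloid list stands at 8.93 and 8.80 in Rip-B7xAI4 replicates 1 and 3 and between 6.00 and 6.36 in the other 4 arrays, and the erythroid list stands at 8.31 in Rip-B7xAI4 replicate 3.

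The count of genes past an adjusted p of 0.05 in limma was 2 without AI4 replicate 1, 22 without Rip-B7xAI4 replicate 2, and 0 without AI4 replicate 2, AI4 replicate 3, Rip-B7xAI4 replicate 1 or Rip-B7xAI4 replicate 3. Of the 22, 7 belong to the myeloid list (Cybb, S100a8, S100a9, Cd68, Mpeg1, H2-Ab1 and C1qc), and 0 to the further myeloid genes described at the end. Of the same 22, 21 were higher in Rip-B7xAI4 replicates 1 and 3, where myeloid markers were high, than in the other 4 arrays. That fit kept only these Rip-B7xAI4 arrays, so it favoured genes high in both. At an unadjusted p under 0.01 the count was 184 without Rip-B7xAI4 replicate 1 against 293 with all arrays.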

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

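The fit without Rip-B7xAI4 replicates 1 and 3 together and the fit with the myeloid marker mean as a covariate were chosen only after the results were seen, and the pseudocount alternative was not run because the values were already log2. Of 93 named genes followed through the settings, 87 kept their direction in all settings run. So did 21 of 27 lists by camera, and Ccl3 stayed between 3.74 and 4.19 on the log2 scale. Many of these genes were named for a small p in the same arrays, so a kept direction was likely in advance and does not measure stability. The 6 genes that turned were all from the set that is always named. The count of genes past the limit, 1 and higher, was 0 with the replicate block. Deviations of same-numbered arrays from their group means correlated at -0.0821, 0.0565 and -0.221, so these arrays were not taken as pairs. With the block 17 lists passed, with interferon-gamma response lost (camera adjusted p = 0.0907). Members past the limit over the list alone went there from 2 to 14 for myeloid markers, 1 to 3 for type I interferon and 1 to 0 for interferon-gamma. With 1 array left out the count of genes ranged from 0 to 22, all higher, and the count at an unadjusted p under 0.01 from 184 to 391. Array weights gave 38 genes, 35 higher and 3 lower, and 734 at an unadjusted p under 0.01. The weights, estimated from the same arrays, were 2.645 for AI4 replicate 2, 2.49 for Rip-B7xAI4 replicate 2 and 0.41 to 0.80 for the others. All counts with array weights thus rest largely on 1 array per group. Without Rip-B7xAI4 replicates 1 and 3 together, which leaves 1 array assumed to vary like the AI4 arrays, 0 genes passed, 0 were higher, 166 had p under 0.01 and 11 lists passed. With the covariate, which within Rip-B7xAI4 was low only in replicate 2, 0 genes passed, 0 were higher, 131 had p under 0.01 and 11 lists passed. The 18 lists became 0 with an estimated correlation, where 6 had unadjusted p under 0.05. They became 2 with fry, the cytotoxic and the cytokine lists, and 1 with fry and the replicate block. For other moves the cause was not tested.

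Some differences changed sign. Without Rip-B7xAI4 replicates 1 and 3 together and with the covariate, in that order, Tnf was at -0.17 and -0.18, Egr1 at -0.0875 and -0.113, Lyz2 at -0.96 and -1.28, Ins2 at 0.22 and 0.24, and Ighm at 0.56 and 0.55. Among lists by camera's direction, with list means given, sterol synthesis was at -0.0995 and -0.121, T cell identity at 0.111 and 0.116, and B cell markers at -0.196 and -0.202, while erythroid markers were at -0.127 in the first of these. Ins2 was also at 0.0312 under quantile normalization, 0.024 under median centring and 0.095 with array weights, and Ighm at 0.0364 under median centring and 0.30 with array weights. Sterol synthesis was at -0.0126 with array weights, acinar markers at -0.0311 under quantile normalization and 0.0229 with the 50% filter, and CD4 and regulatory T cell markers at 0.0566 with that filter. With 1 array left out, Ctla4 was at -0.0014 without AI4 replicate 2, Ins2 at 0.186 without Rip-B7xAI4 replicate 1, and Ighm at 0.0147 without AI4 replicate 1, 0.133 without Rip-B7xAI4 replicate 1 and 0.102 without Rip-B7xAI4 replicate 3. Sterol synthesis was at -0.118 without Rip-B7xAI4 replicate 1, T cell identity at -0.0694 without AI4 replicate 3 and -0.003 without Rip-B7xAI4 replicate 3, and CD4 and regulatory T cell markers at -0.0433 without AI4 replicate 2. Over the 6 fits with 1 array left out, Ctla4 reached 1.38, Ins2 was as low as -0.17, Ighm lay between -0.33 and 0.133, sterol synthesis reached 0.148, T cell identity was as low as -0.350, and CD4 and regulatory T cell markers reached 0.274. The cause was not tested. No measure of background was used here, so it is not known which values lie above it.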

Other observations

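The gene families, the further myeloid genes, the explanations and the tests of them given here were chosen only after the results were seen, while the counts of splits were planned. Of 7 families tested with camera, 4 were higher in Rip-B7xAI4 and 0 of the 7 passed with an estimated correlation. The families were not run after quantile normalization. Among 26 S100, annexin and galectin genes, many of them calcium-binding or sugar-binding proteins, 9 rose when p was adjusted over the family alone. These included the myeloid list members S100a8 and S100a9. S100a9 stood at 11.84, 7.68 and 11.59 in Rip-B7xAI4 replicates 1, 2 and 3 and at 6.19 to 7.29 in AI4, and S100a8 at 10.46, 6.01 and 9.46 and at 4.71 to 5.24. Anxa2 differed by 2.91 ± 0.42 (SE), S100a6 by 2.07 ± 0.30, S100a10 by 1.13 ± 0.19 and S100a4 by 1.96 ± 0.53, and the family had a mean difference of 0.94 (camera adjusted p = 9.28e-07; adjusted p = 0.0967 with an estimated correlation). Of 41 proteasome genes, 37 had a positive difference and 1, Psmb9, rose over the family alone (mean 0.55, camera adjusted p = 3.36e-10; adjusted p = 0.0967 with an estimated correlation).

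Among 26 histone genes, 4 rose adjusted over the family alone, H1f5 by 1.63 ± 0.23 (SE), H2ac15 by 1.46 ± 0.21, H2bc4 by 2.67 ± 0.39 and H2az1 by 0.75 ± 0.16, with values that are uncertain because histone genes have near-identical copies. The histone family had a mean of 0.57 (camera adjusted p = 8.11e-07; adjusted p = 0.117 with an estimated correlation). Killer cell lectin-like receptor genes had a mean of 0.93 over 8 genes (camera adjusted p = 0.000568; adjusted p = 0.0967 with an estimated correlation). Their median was 0.73, and 0.39 for Rip-B7xAI4 replicate 2 alone, where natural killer markers stood at 6.80 against 8.32 and 8.44 in replicates 1 and 3. The 2 members that rose over the family alone, Klra3 and Klrc1, also belong to the natural killer and inhibitory receptor lists. Ribosomal protein genes (mean -0.09, adjusted p = 0.190), kinesin genes (mean 0.27, adjusted p = 0.190, median -0.10) and Gimap genes (mean 0.05, adjusted p = 0.703, median -0.09) did not pass.

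Cytotoxic and cytokine genes were higher in Rip-B7xAI4, where myeloid markers were high in 2 of 3 arrays. With the myeloid marker mean as a covariate, all 11 list members that had passed over the list alone still passed. Lyz2 moved from 2.33 to -1.28, but it belongs to the marker list, so its move does not test the covariate. Within Rip-B7xAI4 only replicate 2 had a low marker mean, so this fit rests largely on that array. Its cytotoxic list mean of 8.13 lay above the AI4 arrays (6.86 to 7.29). For that array this argues against myeloid cells as the whole source, but 1 array cannot settle it for the group. Natural killer cells, which sorting on CD8 and the tetramer should remove, remain a candidate source, with a mean difference of 1.46 over 4 tested markers, but effector T cells and myeloid cells also express these genes, and Fcgr3 is in the myeloid list too. The marker mean followed the myeloid arrays, at 8.32, 6.80 and 8.44 in Rip-B7xAI4 replicates 1, 2 and 3 against 6.19 to 6.78 in AI4, and the difference was 0.38 with the covariate, while the cytotoxic list stood at 8.13 in replicate 2. Of the 4 markers, Klra3 did not follow these arrays, at 6.66, 6.76 and 6.57 in the same order against 4.73 to 5.67 in AI4. With the covariate Klra3 differed by 1.55 ± 0.41 (SE) and still passed over the list alone, so natural killer cells stay open. A larger share of antigen-experienced cells could also give the pattern, with the naive and memory list at -0.70, and cannot be told apart from a change within each cell.

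Cell division genes were higher by a mean of 1.19. With the covariate the mean was 1.12, while the typical standard error of a gene grew from 0.398 to 0.546 and the members past the limit over the list alone went from 17 to 0. The list itself passed camera at the preset correlation with the covariate (adjusted p = 1.84e-17), but did not pass without it with an estimated correlation (adjusted p = 0.245 with an estimated correlation). The member calls ended as the standard errors grew, so the values leave open whether myeloid cells could account for part of the difference.

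Myeloid and dendritic markers were high in Rip-B7xAI4 replicates 1 and 3, for 24 of 26 markers. Non-T cells in those sorts may account for this, although sorting on CD8 and the tetramer should remove them. Of 20 further myeloid genes outside the fixed list, 16 were higher in both arrays than in the other 4 (80%, against 6.75% of all tested genes, one-sided Fisher's exact p = 6.10e-16, with genes not independent), or 15 of 19 without Apoe (p = 7.25e-15), and Apoe, an abundant macrophage transcript picked from the 20 after its values were seen, stood at 11.31 and 10.49 in these arrays and between 7.99 and 8.81 in the others. Induction of these genes in T cells would need Rip-B7xAI4 replicate 2 to be high too, and its mean of 6.28 lay within the AI4 arrays. The median difference of its markers from the AI4 mean was -0.17. Cd68 and Itgax, the 2 markers that rose over the list alone, did lie above all AI4 arrays there. Cd68 stood at 7.35 against 6.21 to 6.49, and Itgax at 6.73 against 5.29 to 5.86. These 2 were picked by p, and 1 array cannot settle whether some of these genes were induced.

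The 6 arrays have 10 splits into groups of 3, too few for a share under 0.05. In each of 3 counts, 1 split, the real one, reached the real value. The real split gave 1 gene past the limit and the highest other 0, 293 genes at an unadjusted p under 0.01 and the highest other 246, and 18 lists and the highest other 11. The 246 came from AI4 replicates 1 and 2 with Rip-B7xAI4 replicate 3 against the rest.

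AI4 replicate 1 correlated with the other arrays at 0.875 to 0.913 across probes, and the other pairs at 0.905 to 0.959. Of 6565 probes with several genes or none named, 0 passed an adjusted p of 0.05 in limma, 102 had an unadjusted p under 0.01 and the lowest adjusted p was 0.250.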
